A study of Escherichia coli str. K-12 substr. MG1655 with 2 samples.

How the data were processed

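Total RNA of Escherichia coli, labelled as K-12 substr. MG1655, was studied in 2 libraries, called library 1 and library 2 after their replicate numbers in the labels. Per the labels' protocols, an overnight LB culture kept at 30 °C was diluted 500-fold and grown on for 3.5 hours to an optical density at 600 nm of 0.30 to 0.35, ribosomal RNA was depleted, and paired-end libraries were built with adapters that carried barcodes of 20 bp. Per the labels' protocols, the libraries were read on 2 ends, with 101 bases in the first run and 51 bases in the second. The series describes both libraries as replicates of 1 bulk RNA sample, so there was 1 group and no contrast between conditions. P-values below therefore measure the difference between these 2 libraries of the same RNA only, and no biological difference.

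Bowtie 0.12.7 was the aligner, per the submitters' processing notes, and the genome was version U00096.2, per the labels. How reads with several matches were placed, how barcodes were grouped into molecules and how fragments were given to genes is not given in the sources used here. The deposited gene tables hold 2 kinds of counts, whole numbers per gene: digital counts, meaning distinct barcoded molecules, and the reads behind them, per the file headers. A second deposited table per library lists each distinct fragment with its start, end, molecules and reads as counts, per the file headers. The authors also deposited RPKM and DPKM values, per the file headers. From the values, RPKM is reads, and DPKM molecules, per kb of gene and per 1000000 assigned to listed genes. In library 1 these normalized values were missing from 926 gene rows, so DPKM was recomputed here from the deposited counts for both libraries. The total implied by the authors' DPKM minus the sum of the listed genes was 0 in both libraries. The row of molecules outside genes was left out of library sizes and tests, and made up 2.37% of the molecules of library 1 (95% Wilson interval 2.27 to 2.47) and 0.862% of library 2 (0.790 to 0.941).

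The fragment table of library 1 listed 5370 positions in 2 rows, and all 5370 crossed a gene boundary. Its sums equalled the gene table for 1288 of 2952 genes, against 2641 of 2641 in library 2. The gene tables were therefore the main source, and fragments inside genes were an added alternative. Analyses of single fragments left out every position listed in 2 rows. Of 3239 gene names, 3209 matched a symbol or synonym of the reference gene table (assembly ASM584v2) and 30 did not. That table was used for names, gene type and gene order, and coordinates are those of the deposited tables. Columns of other series numbered 0.

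A gene without a row in a library was taken as 0 molecules. For each gene with at least 10 counts in sum, the count in library 1 was set against the library's share of all counts in genes by a 2-sided exact binomial test, with Benjamini-Hochberg adjustment and a threshold of 0.05. This was done for molecules and for reads. Log2 ratios of library 2 over library 1 used a pseudocount of 0.5. The variance between libraries was divided by its counting expectation and averaged over genes, with an interval from 2000 bootstrap draws of genes. Correlations across genes used log2(count + 1). For reads in molecule equivalents, reads were divided by the library's mean reads per molecule. Reads per molecule were compared over genes with at least 10 molecules in each library, with 100000 permutations of genes. Genes are not independent replicates, so correlations across genes describe these libraries. Intervals on shares are 95% Wilson intervals and cover counting error only.

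The 21 gene lists, with 468 genes, were fixed before the data were examined: ribosomal proteins, translation factors, RNA polymerase and sigma factors, ATP synthase, glycolysis, the TCA cycle, the respiratory chain, the outer membrane, flagella and chemotaxis, heat shock, cold shock, stationary phase, amino acid biosynthesis, nucleotide biosynthesis, nucleoid proteins, carbon source catabolism, cell division and replication, ribosomal RNA, stable noncoding RNA, small regulatory RNA and cryptic prophage. The median of a list was ranked among 10000 random lists of its size, matched on molecules over 10 bins for the comparisons of reads with molecules and of the libraries. In these comparisons, lists with fewer than 3 measured members were not ranked. The named genes were also fixed by rule: the 10 protein-coding genes with the highest mean molecules per kb, the 2 highest and 2 lowest listed members of each list, the 5 genes at each end of reads per molecule among genes with at least 50 molecules in each library, and the 5 genes at each end of the ratio between libraries among those past the test. Genes outside this rule are said to be so.

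The test was tried on simulated libraries drawn from the means of the genes listed in both, with 200 genes changed. For molecules, 30.9% of 94 genes changed 2-fold and 68.2% of 88 genes changed 4-fold were recovered, and 0 of 1374 unchanged genes were called. For simulated reads, 2012 of 2139 unchanged genes were called. The simulated libraries were scaled by the median of ratios, and molecules were drawn with counting error only. The 0 false calls therefore do not carry over to the calls reported under total scaling. Alternatives were median-of-ratios scaling, TMM scaling from edgeR 4.0.16 in R 4.3.3, other count minimums, leaving out ribosomal and transfer RNA genes, another pseudocount and leaving out each replicate. Chosen after the data were seen were the restriction to genes listed in both libraries, fragments inside genes, and leaving out tufA and tufB. For maxima of reads per molecule, classes of 5 bp were smoothed with a Gaussian kernel of 40 reads. A further test on the stretches without fragments is not reported here. No genome sequence was used here, so GC content was not tested. Every fragment name held a genome position, so the internal standards named in the series design were not analysed here. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.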

Results

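Digital RNA sequencing tags each fragment with a random barcode before amplification, so that distinct molecules and the reads copied from them can be counted separately. The study asked whether counting barcodes in place of reads reduces amplification noise and sequence-dependent bias. It measured the transcriptome of E. coli, labelled as K-12 MG1655, a standard laboratory strain, in 2 libraries made from 1 RNA sample. The strain was not checked by sequence. Library 1 held 83863 molecules from 32733488 reads and listed 2952 genes. Library 2 held 57515 molecules from 26255242 reads and listed 2641 genes. The median listed gene had 7 molecules in library 1 and 6 in library 2, so most single genes were measured with a large counting error. In all, 3239 genes were listed in either library and 2354 in both.

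In the mean of both libraries, the most abundant messages encoded envelope proteins, chaperones and other proteins of growing cells. This ranking took genes without a row as 0, which lowered the ribosomal protein genes that only library 1 listed. The porin gene ompF (985117 to 986205 on the chromosome, genome U00096.2) had the highest level of the protein-coding genes, at 21812 ± 3772 molecules per kb per 1000000 molecules in genes (SD, n = 2), from 1707 and 1520 molecules. It was followed by lpp, the major outer membrane lipoprotein, at 17648 ± 2147, and by acpP, the acyl carrier protein of fatty acid synthesis, at 10312 ± 591. The nucleoid protein gene hupA stood at 9829 ± 1816 and the ribosomal protein gene rpmI at 8244 ± 492. The chaperone genes groS, groL and dnaK stood at 7901 ± 459, 7120 ± 788 and 7033 ± 1026. The superoxide dismutase gene sodA and the cold shock gene cspA completed the 10 highest, at 7328 ± 461 and 7265 ± 1890. Levels of library 2 are relative to a smaller set of listed genes than those of library 1, which raised them by 0.30 on the log2 scale. In library 1 alone, 7 of the 10 highest protein-coding genes encoded ribosomal proteins, from rpsJ at 11352 to rpsU at 8821, and none of these 7 was listed in library 2.

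Of the 21 gene lists, 15 had a median level of their listed members above the 97.5 percentile of random lists of listed genes. Members without a molecule in either library were left out of these medians, among them 26 of the 52 genes of flagella and chemotaxis and 7 of the 21 small regulatory RNAs. Genes named as leading or highest in a list are so in molecules per kb. Stable noncoding RNAs stood highest: ssrA, the tmRNA that rescues stalled ribosomes (2753615 to 2753977), had 1508 and 1589 molecules, and rnpB, the RNA of ribonuclease P, had 1047 and 1014. This list of 4 genes took 3.44% of the molecules in genes of library 1 (95% Wilson interval 3.31 to 3.56) and 5.02% of library 2 (4.84 to 5.20). The TCA cycle took 4.86% and 5.71%, led per kb by sucB (406 and 325 molecules) and the citrate synthase gene gltA (363 and 322), while the longer genes sucA (662 and 571) and acnB (630 and 530) held more molecules. The outer membrane list took 4.73% and 5.98%, led by ompF and lpp and with bamB and lptD lowest. The heat shock list took 4.23% and 4.99%, from groS down to lon per kb. The protease gene lon had 1 molecule in each library, and its neighbour clpX 147 and 132. The respiratory chain took 2.80% and 3.67%, led per kb by cyoA (177 and 172 molecules) and nuoA, with cydA and ndh lowest. ATP synthase took 1.97% and 2.45%, led by atpF and atpA, and glycolysis 1.59% and 1.79%, led by gapA (478 and 385 molecules) and fbaA. Translation factors took 2.26% and 2.64%, led by fusA (1038 and 887 molecules) and infC, with prfC and prfA lowest.

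Amino acid biosynthesis took 1.98% and 2.30%, led by argH (132 and 117 molecules) and argC, while trpD and lysA had 2 or fewer molecules in each library. Cell division and replication took 0.948% and 0.987%, with minD and ftsZ highest. Nucleoid proteins took 0.609% and 0.702%, with hupA and hupB highest, and small regulatory RNAs 0.286% and 0.340%, led by csrC (99 and 77 molecules) and sgrS. Flagella and chemotaxis took 1.23% and 1.47%, and this came from part of the list. All 14 flg genes, most of them for the hook, rod and rings of the flagellum, were listed, with 930 and 778 molecules in sum and flgD and flgB highest per kb. None of the 20 fli genes of the list was listed in either library, and whether the strain sequenced carries them was not tested by sequence. The chemotaxis genes cheW and cheA had 1 molecule each, in library 1 and library 2. Ribosomal proteins and RNA polymerase completed the 15, but only in the mean of both libraries and in library 1. In library 2 alone their medians stood at the 0 and 0.185 percentiles.

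The other 6 lists did not pass the 97.5 percentile. Cold shock genes stood at the 95.3 percentile, and at 98.2 in library 2 alone, with 536 and 393 molecules, led per kb by cspA and cspC and in molecules by pnp (240 and 179). Carbon source catabolism stood at the 92.7 percentile, with large differences between systems. The maltose genes malE (442 and 436 molecules) and malM (233 and 180) led this list per kb, whereas rbsA and araB had 1 molecule in library 1 and were not listed in library 2. Nucleotide biosynthesis stood at the 60.2 percentile, led by purA and carA. Stationary phase genes stood at the 25.5 percentile, and at the 19.1 and 4.92 in each library alone, with 48 and 58 molecules in sum, of which uspA and dps had the most. Ribosomal RNA, depleted before sequencing, had 6 and 22 molecules, all in rrlA and rrsH, the 2 listed genes of the 22 in this list. The placing of reads shared between gene copies is not given, so these counts do not measure how much ribosomal RNA remained. The cryptic prophage list had 18 and 4 molecules, of which hokD had 16 and 4, and stood at the 0.105 percentile in the mean and at the 4.46 and 4.48 in each library alone. Only 3 of its 18 genes were listed in either library, and whether the strain sequenced carries the others was not tested by sequence.

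**Figure D1:**
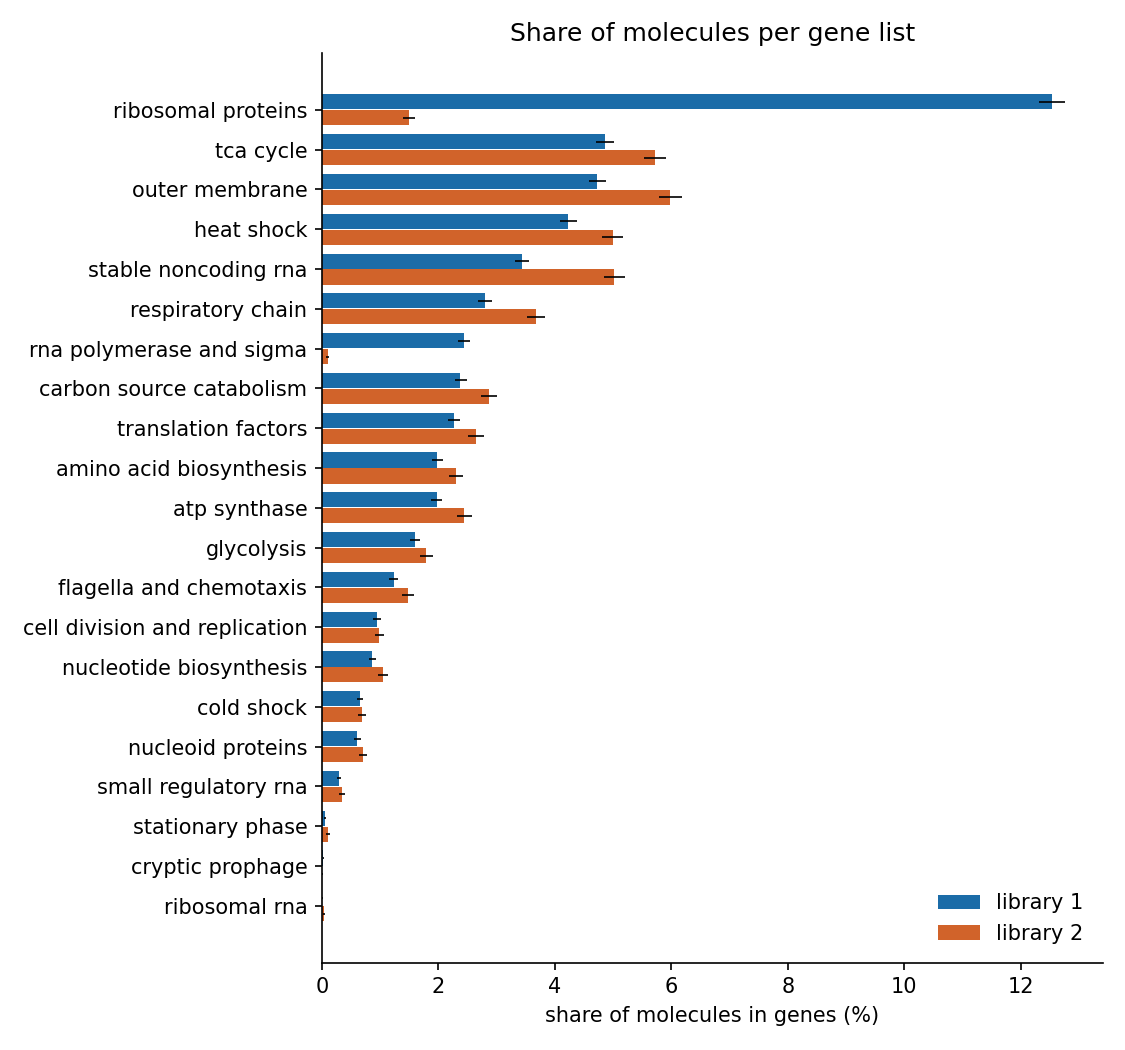
Share of the molecules in genes (percent, horizontal axis) taken by each of the 21 gene lists in library 1 and library 2, with 95% Wilson intervals. Ribosomal proteins took 12.5% in library 1 and 1.49% in library 2, where 4 of the 54 genes were listed, while the TCA cycle took 4.86% and 5.71%.

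Between the libraries, 205 of 1649 genes differed in molecules by the exact binomial test with Benjamini-Hochberg adjustment, 73 higher and 132 lower in library 2. Of the lower genes, 131 had no molecule listed in library 2. A gene without a row was taken as 0, so these calls do not tell an absent row from an absent transcript. The 5 with the smallest ratio were rpoA, rpoB and rpoC of RNA polymerase, secY of the protein translocase and rplB of the ribosome, with 693, 519, 480, 496 and 434 molecules in library 1 and none listed in library 2 (largest adjusted p = 1e-97, exact binomial test). The 5 with the largest ratio were the transfer RNA genes metW, glyX, alaW, glnW and valY, with 15, 13, 13, 11 and 10 molecules in library 2 and none listed in library 1. These 5 had only 109 to 204 reads per molecule in library 2, against a median of 457 over the 914 genes with at least 10 molecules in each library. Transfer RNA genes with near-identical copies are uncertain, because the placing of shared reads is not given. Scaling by the median of ratios moved all log2 ratios by -0.33 and gave 168 genes, 15 higher and 153 lower, so lower genes went from 64.4% to 91.1% of the calls.

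Over the 2354 genes listed in both libraries, a restriction chosen after the data were seen, 8 of 1501 tested genes differed, and 95 had an unadjusted p under 0.05. The cold shock gene cspA (150 and 72 molecules, log2 ratio -0.83, adjusted p = 0.011) and the aspartate pathway gene asd (53 and 16, -1.47, adjusted p = 0.0202) were lower in library 2 by the exact binomial test. The transfer RNA genes glyV, valU and valX, the ribosomal RNA gene rrlA, the elongation factor gene tufA and ssrA were higher. For ssrA the log2 ratio was 0.30 (adjusted p = 7.3e-06, exact binomial test) and for tufA 1.05 (adjusted p = 5.76e-05). tufA has a near-identical copy, tufB, and its value is uncertain. Molecules counted outside genes across its border with fusA went the other way (78 and 8). How fragments were given to genes may therefore also have moved the value of tufA. The value of rrlA is uncertain too, because the placing of reads shared between gene copies is not given. asd, glyV, valU and valX were named after their values were seen.

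**Figure D2:**
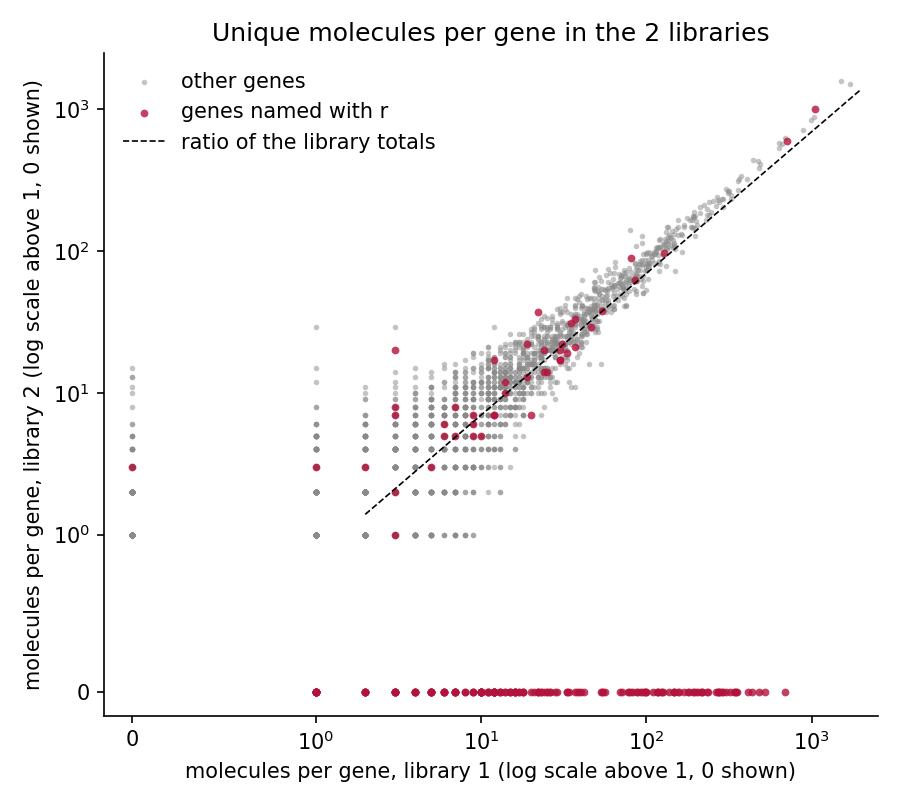
Unique molecules per gene in library 1 (horizontal axis) and library 2 (vertical axis), on scales that are logarithmic above 1 and show 0, with genes whose name begins with r in red. Red points lie on the line at 0 molecules in library 2 up to 693 molecules in library 1 (rpoA). Most other genes lie along the dashed ratio of the totals but centre above it. Scaling by the median of ratios moves log2 ratios by -0.33 against that line.

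Among gene lists, ribosomal proteins separated the libraries most, through genes without a row in library 2, which were taken as 0. All 54 genes had molecules in library 1 and took 12.5% of the molecules in genes (95% Wilson interval 12.3 to 12.8), and 4 genes were listed in library 2, taking 1.49% (1.39 to 1.59). The test called 52 of the 54, 50 of them lower with none listed in library 2, and adjusted over the list alone it called 52. The lowest listed members were rplS and rpmG, with 55 and 25 molecules in library 1. The 4 members listed in both, rplT, rpmI, rpsA and rpsO, had a median log2 ratio of -0.10 under totals of the genes listed in both, and 0 of the 4 differed. Of RNA polymerase and sigma factor genes, 7 of 9 tested members were lower with none listed in library 2, from rpoA to rpoH (23 molecules), adjusted over all genes and adjusted over the list alone. The genes rpoS (33 and 19 molecules) and rpoN (37 and 33) were listed in both libraries, and fecI had 3 molecules in library 2. The median ratios of ribosomal proteins and RNA polymerase ranked at the 0 and 0.015 percentiles of matched random lists. These ranks follow from taking genes without a row as 0.

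Stable noncoding RNAs ranked at the 99.6 percentile, with a median log2 ratio of 0.54, and 3 of 4 members were called higher in library 2, also adjusted over the list alone. Among genes listed in both libraries 1 of the 4, ssrA, was called. The respiratory chain ranked at the 98.1 percentile, with 7 of 21 members called higher, also adjusted over the list alone, but 0 were called by the median of ratios or among genes listed in both. Its rank fell inside the range by reads (84.3) and among genes listed in both (94.4). The other 14 ranked lists lay between the 24.5 percentile of translation factors and the 83.1 percentile of nucleoid proteins. Over these 14, calls were 4 in translation factors and the outer membrane, 3 in ATP synthase, the TCA cycle and heat shock, 2 in nucleotide biosynthesis, carbon source catabolism and cell division, 1 in flagella and cold shock, and 0 in glycolysis, amino acid biosynthesis, nucleoid proteins and small regulatory RNA. With the median of ratios, the calls fell to 2 in translation factors, 1 in the TCA cycle and 0 in the outer membrane, ATP synthase and heat shock, and rose to 4 in cell division. Nucleotide biosynthesis again had 2, but carA was no longer called and another gene was. The calls fell to 1 in carbon source catabolism and 0 in flagella. Cold shock again had 1 call, but of another gene and direction. By the median of ratios it was cspA, lower in library 2 (log2 ratio -0.86, adjusted p = 0.000315, exact binomial test), while the call under total scaling was higher. Among genes listed in both, 1 was called in translation factors, 1 in cold shock and 0 in the other 12 lists. Adjusted over the list alone, the calls became 4 in heat shock, 3 in nucleotide biosynthesis and carbon source catabolism and 2 in cold shock, and were equal in the rest. Ribosomal RNA, stationary phase and cryptic prophage had fewer than 3 tested members, with 1, 0 and 0 calls, and adjusted over the list alone 1, 1 and 0.

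Counted by reads, 3076 of 3218 genes differed between the libraries by the same test, which treats copies of 1 molecule as independent. Among genes listed in both, 2171 of 2354 differed by reads, against 8 of 1501 by molecules. For genes listed in both, the variance between libraries was 1.25 times the counting variance for molecules (95% bootstrap interval 1.14 to 1.36), against 533 times for reads. Put in molecule equivalents, reads gave 1.49 times the counting variance (1.34 to 1.65), and the ratio of reads to molecules was 1.19 (1.10 to 1.29). The SD of the log2 ratio over these 1501 genes was 0.68 for molecules and 0.74 for reads. Across the 2354 genes listed in both, Pearson's r of log2(count + 1) was 0.929 for molecules and 0.837 for reads, and Spearman's rho 0.893 and 0.878. Over all 3239 genes, r was 0.718 and 0.290 and rho 0.685 and 0.673, and the variance ratio for molecules was 8.31. The same 1 was added to both measures, although 1 molecule stood for 390 reads in library 1 and 456 in library 2. The values of r for molecules and reads are therefore not on a like scale, and their difference does not measure amplification noise.

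Reads per molecule varied little between genes and followed the gene only weakly from library to library. Over 914 genes with at least 10 molecules in each library, the median was 389 reads per molecule in library 1 and 457 in library 2, with coefficients of variation of 13.6% and 11.1%. The genes rpmI (457 and 470), csrC (435 and 509), accA, hflX and miaA had the highest values relative to the medians of both libraries among genes with at least 50 molecules in each. The lowest of these were tufA (165 and 452), flgF (328 and 393), thrU, bamC and adk. The values of both libraries correlated across these genes with r = 0.098 (permutation p = 0.00306, adjusted 0.0049) and rho = 0.119 (permutation p = 0.00024, adjusted 0.00128). Over the 239 genes with at least 50 molecules in each library, r was 0.196. The p-values of the correlations adjusted here belong to a family of 8 computed on 4 sets of genes or fragments. For 1282 single-molecule fragments with the same start and end in both libraries, r was 0.045 (permutation p = 0.105) and rho 0.0997 (permutation p = 0.00048, adjusted 0.00128). The variance of reads per molecule over genes was 1.67 and 1.24 times that of random draws of the library's own single-molecule fragments. Random draws thus gave much of the spread, which lowers r. A weak r therefore does not show that gene-dependent bias is absent.

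**Figure D3:**
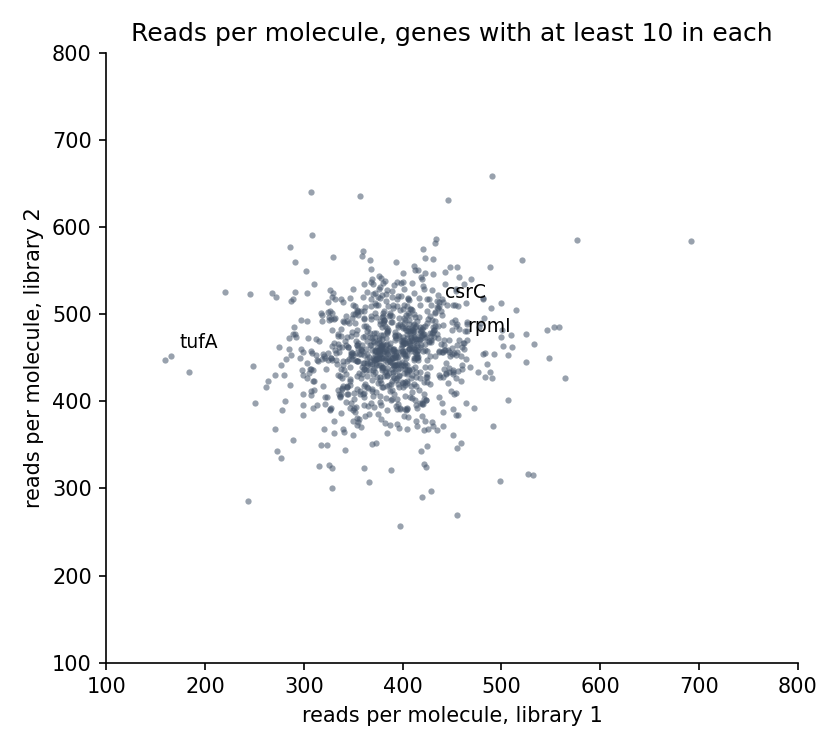
Reads per molecule of 914 genes with at least 10 molecules in each library, library 1 on the horizontal and library 2 on the vertical axis. The points form a round cloud around the medians of 389 and 457, with r = 0.098, and tufA lies at the left edge at 165 in library 1.

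Reads against molecules differed for a single functional group in both libraries. The 6 small regulatory RNA genes with at least 10 molecules in each library, among them csrC and sgrS, had more reads than their molecules by a median log2 of 0.19 in library 1 and 0.16 in library 2, at the 99.2 and 99.0 percentiles of matched lists. At least 50 molecules in each library left too few members to rank this list. The random lists were matched on molecules but not on length. The fall of reads with fragment length, given below, was therefore not separated from this group. Ribosomal proteins, with 4 members, reached the 99.8 percentile in library 1 and the 64.5 in library 2, and glycolysis the 73.5 and 97.8. The mean of both libraries put amino acid biosynthesis at the 0.68 percentile, but each library alone put it at the 9.92 and 48.4. The other 13 ranked lists lay between the 2.5 and 97.5 percentiles in each library and in the mean.

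Reads per molecule fell with fragment length. The median fragment was 79 bp in library 1 and 65 bp in library 2. Mean reads of single-molecule fragments fell from 487 ± 7 (SE, 1306 fragments) at 28 to 40 bp to 185 ± 5.9 (SE, 390 fragments) above 150 bp in library 1. In library 2 they fell from 517 ± 5 (SE, 2330 fragments) to 178 ± 9.1 (SE, 241 fragments). Spearman's rho of reads with length was -0.230 over 71018 fragments and -0.254 over 54268 fragments. Across genes, gene length and reads per molecule had a rho of -0.005 in library 1 and -0.080 in library 2. GC content was not tested, as no genome sequence was used.

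**Figure D4:**
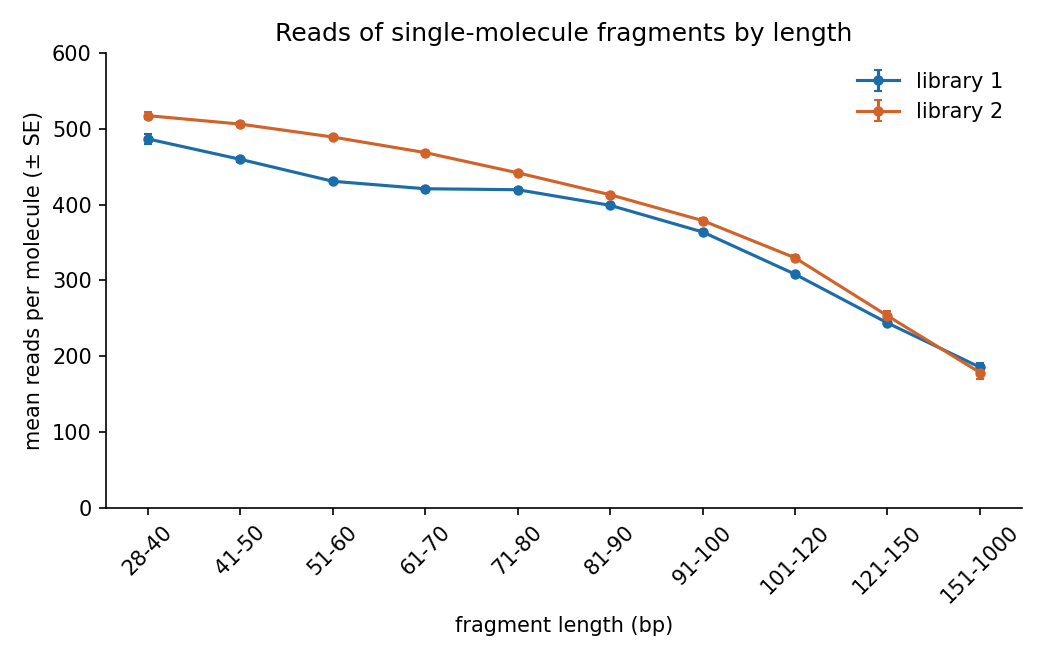
Mean reads of single-molecule fragments (vertical axis, with SE) by fragment length class in bp (horizontal axis), for library 1 and library 2. The means fall from 487 and 517 in the shortest class to 185 and 178 in the longest.

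Single molecules differed widely in reads, with a coefficient of variation of 0.545 in library 1 and 0.491 in library 2, and 1.44% and 1.36% of single-molecule fragments had 1 read. Over the 18 length classes of 5 bp from 30 to 119 bp, each with at least 300 fragments in both libraries, the distribution above 100 reads had 2 maxima in 18 classes of library 2 and in 12 of library 1. In library 1 the 6 classes from 90 bp on had 1 maximum. Over the classes with 2 maxima, the upper lay at a median of 1.86 times the lower in library 1 and 1.98 times in library 2.

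**Figure D5:**
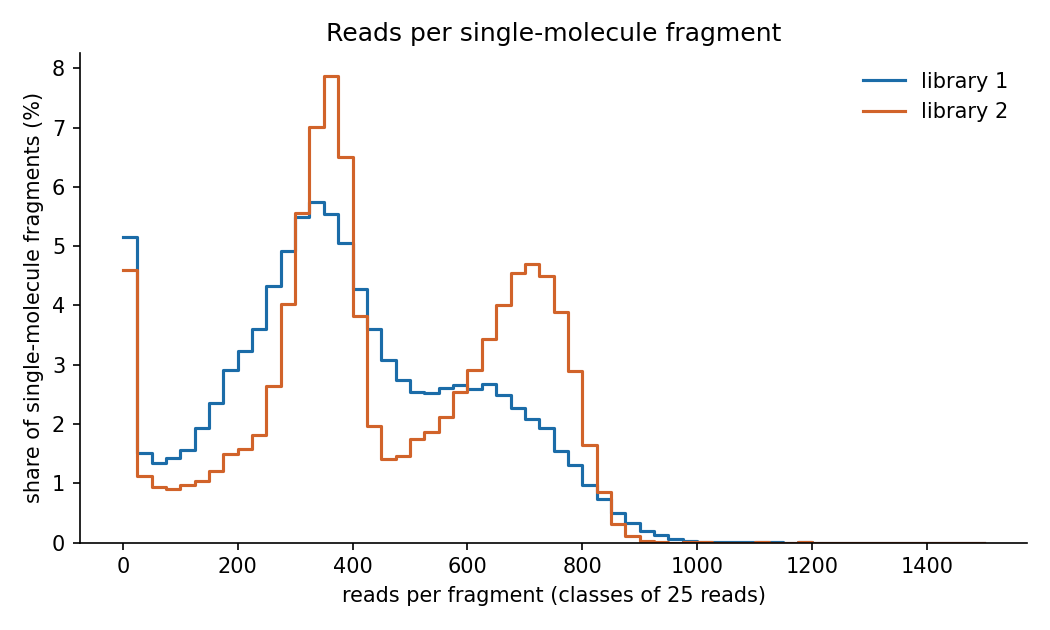
Distribution of reads per single-molecule fragment (horizontal axis, classes of 25 reads) as percent of fragments (vertical axis) in library 1 and library 2. Above 100 reads, library 2 has 2 separate maxima and library 1 a high and a low, broad one, and both have a further maximum under 25 reads.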

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

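Molecules outside genes were not used in the comparisons and lay above the 3 counts that a count of 0 allows. They numbered 1986 in library 1 and 496 in library 2. The stretch from 761830 to 762351, at the border of the TCA cycle genes sucB and sucC, held 107 and 58 molecules, and the stretch from 1150555 to 1150959, from the end of fabG into acpP of fatty acid synthesis, held 74 and 29. The stretch from 127638 to 127970, at the border of aceF and lpd of pyruvate dehydrogenase, held 34 and 23. The stretch from 3469264 to 3469492, across the border of tufA and fusA, held 78 and 8, and it overlaps both genes. Positions that cross a gene boundary were listed in 2 rows in library 1 (5370 positions) but not in library 2. Counts outside genes may therefore not be alike between the libraries. These stretches were chosen after their values were seen.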

How the results depend on the processing

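The restriction to genes listed in both libraries, fragments inside genes, and leaving out tufA and tufB were chosen after the data were seen. Of 43 results recomputed under an alternative for the comparisons, 30 kept their side of the threshold or stayed within their interval or 1.5 times the count reported, and 13 moved. The balance of higher and lower genes reversed with the scaling by reads, from 1816 higher and 1260 lower to 1355 and 1687 with the median of ratios and 1391 and 1644 with TMM. By molecules it went from 73 higher and 132 lower to 6 and 2 among genes listed in both libraries, and kept its direction under the other settings. Under the restriction to genes listed in both libraries, genes differing by molecules went from 205 to 8, the variance ratio from 8.31 to 1.25 for molecules and from 2284 to 533 for reads, Pearson's r from 0.718 to 0.929 for molecules and from 0.290 to 0.837 for reads, and lists outside the 2.5 to 97.5 percentiles between libraries from 4 to 1 (3 by reads). By construction it removes genes at 0 in either library, and it recomputes the totals as well, a shift of -0.30 on the log2 scale. At least 50 counts in sum gave 136 genes of 573 differing by molecules and a variance ratio of 19.5, with fewer genes tested. At least 50 molecules in each library gave 1 list outside the range for reads against molecules in place of 2: small regulatory RNA then had too few members, amino acid biosynthesis moved inside (5.47) and ribosomal proteins moved outside (98.3). A pseudocount of 0.1 lowered r to 0.527 for molecules and 0.196 for reads, and genes with at least 10 molecules in sum gave 0.483 and 0.0942; the cause was not tested. Genes differing by molecules were 168 with the median of ratios (147 shared with the reported 205), 169 with TMM, 183 without a filter, 197 without ribosomal and transfer RNA genes and 159 from fragments inside genes. Genes differing by reads ranged from 2171 to 3078. The correlation of reads per molecule was 0.196, 0.060 and 0.101 under its alternatives, each with a permutation p under the threshold. Leaving out replicate 1 or 2 gave 14 and 15 lists above the 97.5 percentile, against 15. For single lists and genes, 214 of 226 values stayed on their side of the threshold. The check against GC content and the test of internal standards by reads were not run. No paired analysis was possible because there is 1 group. Depth limited the test: 30.9% of tested genes changed 2-fold were recovered in simulated libraries scaled by the median of ratios, and the median listed gene had 6 to 7 molecules.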

Other observations

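Genes outside the lists, chosen here after their values were seen, also had many molecules. The lactate genes lldP (318 and 265 molecules) and lldD (313 and 264), which encode a permease and a dehydrogenase, the trehalose-6-phosphate hydrolase gene treC (323 and 250) and yjiY (685 and 633), which encodes a membrane transporter, are examples, against 662 and 571 molecules of the TCA cycle gene sucA. Transfer RNA genes numbered 41 in library 1 and 66 in library 2, with 354 and 652 molecules, or 0.432% and 1.14% of the molecules in genes. Of 27 tested transfer RNA genes, 11 were called, all 11 higher in library 2, and 3 were called among genes listed in both libraries. They had 316 and 326 reads per molecule, against 390 and 458 for protein-coding genes. No biological difference between groups was tested, because the design has 1 group, and all tests of explanations below, with their bounds and the choice of genes of the BL21 genotype, were chosen after the result was seen, and that of ribosomal protein transcripts was replaced more than once.

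Of 929 genes with at least 15 molecules in library 1, 113 had no molecule listed in library 2; lower depth is argued against, since they were expected at a median of 76.1 molecules there. For the 63 that encode no ribosomal protein (55.8%), fewer ribosomal protein transcripts in the second preparation is argued against, because 39 of them, such as rho (351 molecules in library 1) and rnb (78), had no missing ribosomal protein gene within 10 listed genes. For the 50 ribosomal protein genes it stays open, because no value here separates it from units left out of the table: 41 stretches beside missing genes of any kind also lost molecules (479 and 53, log2 ratio -2.97, 95% interval -3.38 to -2.56), which both would give, and 1 of the 41, beside rpmB, held all 53, while the 4 ribosomal protein genes listed in both libraries, with a median of -0.10, are too few to exclude it. The missing genes followed the alphabet: 81.4% of genes named with r were missing (96 of 118), against 2.10% of the others (17 of 811; 2-sided Fisher's exact p = 3.18e-90), and 12 of those 17, such as secY and tsf, lay within 2 genes of a missing r gene. A candidate explanation is that transcription units whose name begins with r were left out of the tables of library 2 before the authors' scaling, since the column of gene names is headed TU and r genes such as rpsA remained.

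Both libraries lacked fragments over the same long stretches, 20 of them over 10 kb and 335 kb in sum, the longest from 1992617 to 2036354 (43.7 kb, between uvrC and yedW, where the fli genes lie), then from 262178 to 296601 and from 2753981 to 2786977. Rows left out after the authors' scaling are argued against, because the implied totals differed from the listed sums by 0. Low expression alone is argued against for the fli genes of the longest stretch. None of the 20 fli genes was listed, while the flg genes, which share a master regulator with them, had 930 and 778 molecules. For other genes and the shorter stretches it stays open. The longest run of unlisted neighbouring reference genes was 55, against at most 48 in 1000 shuffles of blocks of 10 genes. Such blocks break up longer runs of silent neighbours, so the shuffles cannot decide. Where this run lies was not recorded. A strain other than the labelled one, such as one of the E. coli B line that lacks these segments, may be a cause but stays open: of 4 genes in the usual genotype of BL21, a B-line strain, ompT and dcm lie inside such stretches and so add nothing. The other 2, hsdS (1 and 0 molecules) and lon (1 and 1), had at most 1 molecule in each library. Their listed neighbours hsdM (28 and 15) and clpX (147 and 132) had more. Of 4290 protein-coding genes, 39.7% also had at most 1 molecule (1-sided Fisher's exact p = 0.157). Both genes being low is the most extreme outcome that 2 genes allow. The test therefore could not pass the threshold whatever the counts, and its p-value counts neither for nor against another strain. Of the 18 genes of the cryptic prophage list, 3 were listed in either library, which low expression or absent genes would both give. No sequence was used here.

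Reads per single-molecule fragment had 2 maxima in library 2 and, up to 89 bp, in library 1. Different molecules with the same position and barcode are argued against, because at least 32.5% of fragments in the classes with 2 maxima lay above the minimum between them, while 2.51% and 2.32% of positions had 2 or more counted molecules. A mixture of fragment lengths as the whole cause is argued against, because 2 maxima were seen in 66.7% of the 18 length classes of 5 bp in library 1 and in 18 of 18 in library 2. Amplification of 1 or 2 strands of a fragment, which needs a ratio near 2, may explain the maxima but stays open: the median ratio was 1.98 in library 2 (range 1.74 to 2.04) and 1.86 in library 1 (1.73 to 1.96). Within bounds of 1.8 to 2.2 lay 17 of 18 classes of library 2 and 8 of 12 of library 1, whose maxima merged in the 6 classes from 90 bp on.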
